A study of Homo sapiens with 12 samples.

How the data were processed

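Polyadenylated RNA of K-562 cells was measured by strand-specific RNA sequencing in 12 libraries: untreated cells and cells after 8, 24 and 48 h in 5 µM Si-711, with 3 independently grown replicates for each of the 4 groups. RNA extraction and library construction were carried out by a sequencing company. The submitters' processing notes name cutadapt, Salmon and DESeq2 and the genome build GRCh38, without versions, and the annotation release is not given in the sources used here.

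The deposited table holds a signal for 51112 Ensembl gene identifiers in each library, namely gene counts that the authors normalized with DESeq2. The values are not whole numbers. Between 36.6 and 66.6% of the low values of a library lay within 0.1 of a whole multiple of one step, so whole reads were not recovered and methods for counts were not run. That step, taken as the value of one read, was 0.699 to 1.23 normalized counts, and the total divided by it gave about 24600000 to 40400000 reads per library. Totals were 31387546 to 31718907 normalized counts in untreated libraries, 27217438 to 28940867 at 8 h, 27070528 to 28256228 at 24 h and 34614827 to 37117837 at 48 h. The normalization of the authors was kept in the main results, so a shift shared by most genes would not appear in them.

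Symbols were taken for 50026 identifiers from a gene name table and for 267 more from GENCODE release 29, which also gave coordinates on GRCh38, and 819 had none. A total of 840 symbols belonged to more than 1 identifier, and 22912 genes were at 0 in all libraries. Genes with a value of at least 10 in at least 3 libraries were tested, which left 15424. Values were put on the log2 scale after adding 1. Salmon divides reads among similar transcripts by estimation, so values of near-identical genes such as HBA1 and HBA2, HBG1 and HBG2, HSPA1A and HSPA1B, ACTB and ACTG1 or EIF3C and EIF3CL can trade reads.

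Groups were compared with limma 3.58.1 in R 4.3.3, with a mean trend in the prior variance and 1 fit over all 4 groups, from which 5.08 prior degrees of freedom were estimated. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg over the genes tested in each comparison, and an adjusted p under 0.05 was called. The comparisons were 8, 24 and 48 h against untreated, 24 h against 8 h and 48 h against 24 h, with the moderated F-test over the first 3. Fold changes are on the log2 scale with their moderated standard error. The 3 untreated libraries serve all comparisons with untreated cells. Genes were named by a rule fixed before the data were examined: per comparison with untreated cells the 10 largest rises and falls, per successive comparison the 5 largest each way, up to 4 members of a list with the largest change, and SIRT1 and SIRT2. Such genes had to pass the test and have a mean of at least 50, and for the largest changes all treated libraries had to lie beyond all untreated ones. KIT and DDIT3 in the plot of values per library, and MYC at 8 h, were chosen after their values were seen. A few genes that met the rule are not reported here.

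Gene lists were fixed before the data were examined, 37 with at least 5 tested members: sirtuins, NAD metabolism, lysine deacetylases and acetyltransferases, p53 targets, DNA replication, mitosis, CDK inhibitors and cyclins D, globins and erythroid membrane, heme biosynthesis, erythroid and megakaryocytic transcription factors, megakaryocyte and platelet, granulocyte and monocyte, lymphocyte, stromal and epithelial, apoptosis, integrated stress response, ER chaperones, heat shock, NRF2, FOXO, NF-kB, interferon-stimulated, ERK, BCR-ABL1 and STAT5, MYC and ribosome biogenesis, cytosolic ribosomal proteins, OXPHOS, mitochondrially encoded, glycolysis, cholesterol, fatty acid synthesis, LXR, autophagy, tubulins, DNA repair, ABC transporters and core clock genes. Of 819 distinct listed genes, 26 were not found in the table. Members of a list are counted below among the genes that passed the filter on low values. Lists were tested against all other genes with camera of limma at a preset correlation of 0.01, adjusted over the 111 list tests with untreated cells, and again with an estimated correlation, with ranks and with fry. Counts of members are given over all genes tested and adjusted over the list alone. Some genes belong to more than 1 list.

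Alternatives planned before the data were examined were added values of 0.5 and 8, no filter and a mean of at least 50, equal totals, centring on the library median, quantile normalization, a fit of the compared groups alone, a replicate block, a robust prior, a threshold of 0.01 and leaving out each library in turn. Removal of a trend with transcript length and GC content, and omission of 2 sets of genes with doubtful values, were added after the data had been seen. Tested on simulated data with 200 changed genes, the fit for 8 h against untreated gave 5 false calls among 15424 genes. That number holds for the simulated setting and not for the real comparisons, where far more genes were called. Figures and tables used Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9.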

Results

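Bulk RNA sequencing was used to follow gene expression in K-562 cells exposed to Si-711, a compound that the series describes as inhibiting both sirtuin 1 and sirtuin 2, which are NAD-dependent protein deacetylases. K-562 is an established human chronic myeloid leukemia line that carries the BCR-ABL1 fusion and expresses embryonic and fetal globins. Untreated cells and cells kept for 8, 24 or 48 h in 5 µM Si-711 were sampled, with 3 biological replicates in each of the 4 groups and 12 libraries in total. The table summed to between 27070528 and 37117837 normalized counts per library, which corresponded to about 24600000 to 40400000 reads. Between 13755 and 14719 genes per library reached a value of 10. Every treated library differed from the untreated ones in both exposure and time in culture, because no vehicle libraries and no untreated libraries of later times were part of the design.

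Across genes, Pearson's r of the log2 values was 0.964 to 0.974 within groups and 0.882 to 0.966 between groups, ranges that overlapped, and genes are not independent replicates. The first principal component held 46.6% of the variance and the second held 16.5%. On the first, 24 h replicate 1 lay apart from its group, at 20 against -10.1 and -8.7 for replicates 2 and 3. Ribosomal protein genes took 7.6 to 8.3% of the total in untreated libraries and 13.6 to 15.4% at 48 h. Genes of the mitochondrial genome took 3.4 to 3.8% in untreated libraries and 6 to 7.4% at 48 h.

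SIRT1, the gene of one of the named targets (ENSG00000096717, GRCh38 chromosome 10, 67884669 to 67918390), was lower at 8, 24 and 48 h than in untreated cells. It was not called between 8 and 24 h. Its mean was 1550 ± 158 normalized counts (SD, n = 3) in untreated cells, 1120 ± 72.6 at 8 h, 997 ± 13.1 at 24 h and 723 ± 165 at 48 h. The log2 fold changes were -0.45, -0.63 and -1.12 (SE 0.15, limma adjusted p = 0.0337, 0.00316 and 1.52e-05). The call at 8 h was lost with equal totals (-0.29), without the filter on low values, without untreated replicate 1 (-0.45) or 2 (-0.38) and without 8 h replicate 1 (-0.45), 2 (-0.41) or 3 (-0.50). SIRT2, the gene of the other target, was not analysed here. In the sirtuin list, 0, 1 and 0 of 6 members rose and 1, 2 and 3 fell at 8, 24 and 48 h (adjusted over the list alone, 1, 1 and 0 rose and 1, 2 and 3 fell), with camera adjusted p = 0.735, 0.911 and 0.41. SIRT6 fell at 24 h (-0.59, adjusted p = 0.00225) and SIRT5, a mitochondrial sirtuin, rose at 24 h (0.73, adjusted p = 0.00441).

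The first comparison asked which genes had changed after 8 h. All 9 globin genes together summed to 494666 ± 167243 normalized counts (SD, n = 3) in untreated cells, or 1.57% of the total, and to 49479 ± 15459 at 8 h, which was 10-fold lower. HBZ, the embryonic zeta globin (ENSG00000130656, GRCh38 chromosome 16, 152687 to 154503), went from 128000 ± 52200 to 7350 ± 3370 (log2 fold change -4.16, SE 0.37, adjusted p = 1.26e-05). HBG2, a fetal gamma globin, went from 181000 ± 58700 to 17600 ± 5110 (-3.35, adjusted p = 3.92e-06), and HBE1, the epsilon globin, from 18900 ± 6420 to 2080 ± 417 (-3.14, adjusted p = 3.77e-06). Reads of the near-identical pairs HBA1 and HBA2 or HBG1 and HBG2 can be divided unevenly between the members, which leaves their sum untouched. Untreated replicate 3 held 301565 summed counts, against 589167 and 593267 in the other untreated libraries, and the highest 8 h library held 60743.

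The list that joins the globins with erythroid membrane genes was tested as a whole, and 20 of 28 members fell and 0 rose (adjusted over the list alone, 0 rose and 23 fell). The median was -1.26 on the log2 scale (camera adjusted p = 1.27e-11, adjusted p = 0.24 with an estimated correlation). SLC4A1, the band 3 anion exchanger, went from 350 ± 206 to 33.4 ± 24.8 (-3.34, adjusted p = 0.00224, and -4.00 without untreated replicate 3). In the heme biosynthesis list, 9 of 14 members fell and 0 rose (adjusted over the list alone, 0 rose and 10 fell). The median was -0.59 on the log2 scale (camera adjusted p = 2.08e-05, adjusted p = 0.336 with an estimated correlation). ALAS2, the first enzyme of the pathway in erythroid cells, fell by 1.64 on the log2 scale (adjusted p = 0.00095). FAXDC2 fell from 732 ± 381 to 41.4 ± 10.3 (-3.96, adjusted p = 3.85e-05).

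Among the largest rises at 8 h, SLAMF6, a lymphocyte surface receptor, went from 37.2 ± 42.3 to 1310 ± 514 normalized counts (SD, n = 3; 5.67, SE 0.60, adjusted p = 3.85e-05). SIGLEC6, a sialic acid binding receptor, went from 16.5 ± 4.91 to 479 ± 283 (4.66, adjusted p = 1.43e-05). CORO1A, an actin regulator of hematopoietic cells, went from 37 ± 31 to 741 ± 247 (4.62, adjusted p = 3.85e-05), and EVI2B from 17.9 ± 12.7 to 361 ± 129 (4.41, adjusted p = 3.62e-05). Without single untreated libraries the log2 fold change of SLAMF6 was 4.95 (replicate 2) or 6.58 (replicate 3) and that of CORO1A 3.92 (replicate 1) or 5.27 (replicate 3). GGT5 was listed at 1.48, 0 and 6.27 in the untreated libraries and at 204, 154 and 107 at 8 h. In the granulocyte and monocyte list, 7 of 11 members rose and 0 fell (adjusted over the list alone, 7 rose and 0 fell). The median was 1.05 on the log2 scale (camera adjusted p = 6.16e-05, adjusted p = 0.239 with an estimated correlation). LYZ, lysozyme, went from 495 ± 199 to 3190 ± 514 (2.75, adjusted p = 6.83e-06), and SPI1, a myeloid transcription factor, from 385 ± 157 to 1110 ± 95.4 (1.59, adjusted p = 0.00029). In the lymphocyte list, kept as a check for other cell types, 4 of 6 members rose and 0 fell (adjusted over the list alone, 4 rose and 0 fell). The median was 1.75 on the log2 scale (camera adjusted p = 0.00743, adjusted p = 0.309 with an estimated correlation). CD3D, a subunit of the T cell receptor complex, went from 175 ± 85.7 to 617 ± 131 (1.90, adjusted p = 0.000485). In the megakaryocyte and platelet list, 4 of 11 members rose and 0 fell (adjusted over the list alone, 5 rose and 1 fell). The median was 0.89 on the log2 scale (camera adjusted p = 0.0178, adjusted p = 0.335 with an estimated correlation). ITGA2B, the platelet integrin alpha IIb, rose by 2.04 on the log2 scale (adjusted p = 0.000132). The filter on low values left 6 of 18 listed lymphocyte genes, 11 of 23 granulocyte and monocyte genes and 11 of 23 megakaryocyte and platelet genes. It also left 15 of 29 listed interferon-stimulated genes and 18 of 26 NF-kB targets, which are reported below. A gene near 0 in untreated cells could pass it through treated libraries alone, which can favour rises in these lists. In the stromal and epithelial check list, 1 of 8 members rose and 1 fell (adjusted over the list alone, 1 rose and 1 fell; camera adjusted p = 0.779).

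Growth-related lists fell at 8 h. Among MYC and ribosome biogenesis genes, 21 of 28 members fell and 0 rose (adjusted over the list alone, 0 rose and 25 fell). The median was -0.50 on the log2 scale (camera adjusted p = 6.43e-10, adjusted p = 0.373 with an estimated correlation). ODC1, the first enzyme of polyamine synthesis, went from 28800 ± 1420 to 16300 ± 2870 (-0.84, adjusted p = 0.0011). In the DNA replication and G1/S list, 21 of 28 members fell and 0 rose (adjusted over the list alone, 0 rose and 22 fell). The median was -0.48 on the log2 scale (camera adjusted p = 2.77e-09, adjusted p = 0.27 with an estimated correlation). RRM2, a subunit of ribonucleotide reductase, went from 5420 ± 994 to 1400 ± 457 (-1.98, adjusted p = 9.16e-05). In the mitosis and G2/M list, 8 of 28 members fell and 1 rose (adjusted over the list alone, 1 rose and 8 fell). The median was -0.24 on the log2 scale (camera adjusted p = 0.00287, adjusted p = 0.517 with an estimated correlation). AURKA, the mitotic kinase Aurora A, fell by 0.72 on the log2 scale (adjusted p = 0.00145). Among CDK inhibitors and cyclins D, 7 of 12 members rose and 1 fell (adjusted over the list alone, 7 rose and 1 fell). The median was 0.42 on the log2 scale (camera adjusted p = 0.00491, adjusted p = 0.318 with an estimated correlation). CCNG2, cyclin G2, went from 104 ± 11.1 to 430 ± 84 (2.03, adjusted p = 1.23e-05), and CDKN1C, which encodes the CDK inhibitor p57, rose by 1.35 on the log2 scale (adjusted p = 0.000104).

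Stress lists moved in different directions at 8 h. In the integrated stress response list, which holds targets of ATF4, 16 of 24 members rose and 0 fell (adjusted over the list alone, 17 rose and 0 fell). The median was 0.57 on the log2 scale (camera adjusted p = 2.27e-09, adjusted p = 0.24 with an estimated correlation). DDIT4, an inhibitor of mTORC1 signaling, went from 2390 ± 732 to 9620 ± 1660 (2.04, adjusted p = 3.84e-05), and STC2, a secreted glycoprotein, from 319 ± 107 to 1560 ± 178 (2.33, adjusted p = 6.06e-05). In the heat shock list, 13 of 20 members fell and 1 rose (adjusted over the list alone, 1 rose and 13 fell). The median was -0.43 on the log2 scale (camera adjusted p = 0.000419, adjusted p = 0.373 with an estimated correlation). HSPA8, the constitutive chaperone HSC70, went from 125000 ± 4340 to 62900 ± 4790 (-0.99, adjusted p = 0.00119). In the NRF2 oxidative stress list, 13 of 24 members fell and 2 rose (adjusted over the list alone, 3 rose and 15 fell). The median was -0.44 on the log2 scale (camera adjusted p = 0.00526, adjusted p = 0.417 with an estimated correlation). CAT, catalase, fell by 0.87 on the log2 scale (adjusted p = 0.000192). In the interferon-stimulated list, 6 of 15 members rose and 0 fell (adjusted over the list alone, 7 rose and 0 fell). The median was 0.63 on the log2 scale (camera adjusted p = 0.014, adjusted p = 0.24 with an estimated correlation). IFITM2 went from 588 ± 250 to 2830 ± 261 (2.34, adjusted p = 1.35e-05). In the NF-kB target list, 6 of 18 members rose and 1 fell (adjusted over the list alone, 7 rose and 1 fell). The median was 0.52 on the log2 scale (camera adjusted p = 0.0461, adjusted p = 0.379 with an estimated correlation). Among apoptosis regulators, 9 of 26 members rose and 2 fell (adjusted over the list alone, 12 rose and 2 fell). The median was 0.31 on the log2 scale (camera adjusted p = 0.0238, adjusted p = 0.417 with an estimated correlation). BMF, a BH3-only protein that promotes apoptosis, rose by 2.11 on the log2 scale (adjusted p = 0.000639), and BCL2, which opposes it, rose by 1.57 (adjusted p = 0.00143). Among nuclear OXPHOS subunits, 9 of 32 members fell and 0 rose (adjusted over the list alone, 0 rose and 10 fell). The median was -0.19 on the log2 scale (camera adjusted p = 0.000121, adjusted p = 0.417 with an estimated correlation). CYCS, cytochrome c, fell by 0.63 on the log2 scale (adjusted p = 0.000466). Among cytosolic ribosomal proteins, 2 of 32 members fell and 0 rose (adjusted over the list alone, 0 rose and 0 fell). The median was -0.16 on the log2 scale (camera adjusted p = 0.0174, adjusted p = 0.76 with an estimated correlation).

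At 8 h, 4347 of 15424 tested genes changed by the limma test, of which 2001 rose and 2346 fell, and among them 909 rose and 264 fell by 2-fold or more. The split by direction depended on scaling. Changes of 2-fold or more were 1174 up and 177 down with equal totals, 797 and 327 with median centring and 647 and 411 with quantile normalization. The split of all calls was 2887 up and 1083 down with equal totals, which moved the median of all tested genes from -0.01 to 0.14, and 1658 up and 3230 down with median centring, which moved it to -0.10. Without 8 h replicate 2, 1386 genes rose and 1544 fell, 2930 in all. Several list calls were lost with other scalings. Quantile normalization ended those of the mitosis (-0.07), NRF2 (-0.27), OXPHOS (-0.05) and NF-kB (0.35) lists and turned the ribosomal protein list upward (0.13). Equal totals ended those of the megakaryocyte (1.04), NF-kB (0.68) and ribosomal protein (0.00) lists, and median centring that of the apoptosis list (0.22). A required mean of at least 50 ended that of the ribosomal protein list (-0.16). The NF-kB call was lost with ranks (0.52) and, in a setting chosen after the data were seen, with the length and GC trend removed (0.45). Single libraries also mattered. The NF-kB call ended without untreated replicate 2 (0.44), 8 h replicate 1 (0.62) or 2 (0.33) or 24 h replicate 1 or 3 (0.52), the ribosomal protein call without untreated replicate 1 (-0.13) or 8 h replicate 2 (-0.09), and the apoptosis call without untreated replicate 1 (0.24).

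**Figure D1:**
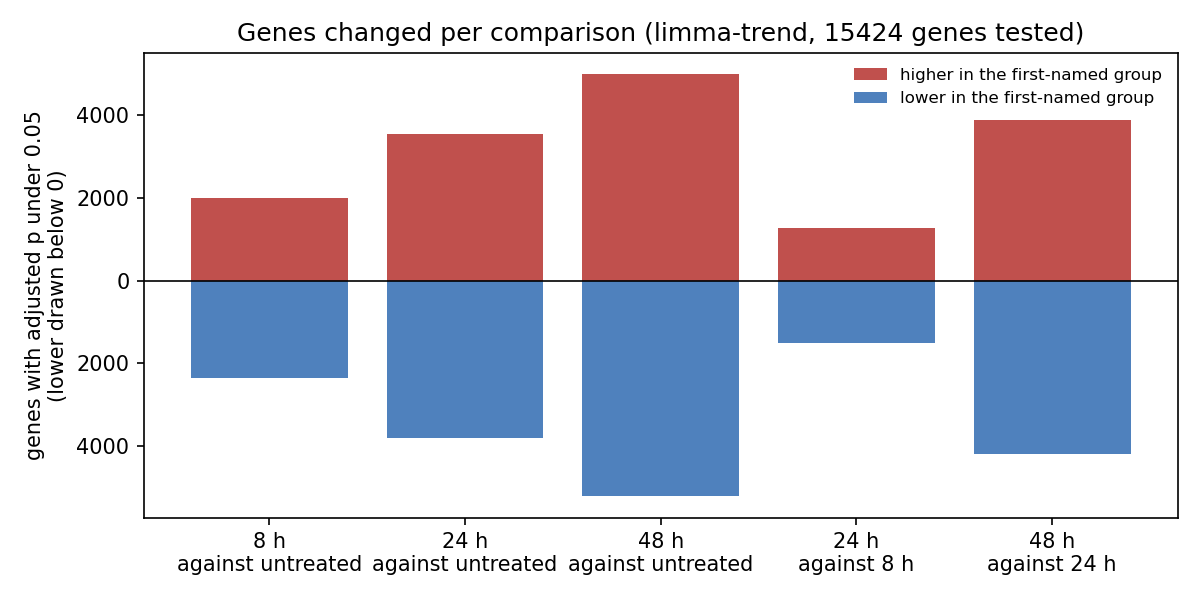
Number of genes with an adjusted p under 0.05 by limma in each of 5 comparisons, with genes higher in the first-named group drawn above 0 and genes lower drawn below it. The bars hold 2001 and 2346 genes for 8 h against untreated and 4989 and 5218 for 48 h against untreated, out of 15424 tested.

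The next comparison asked which genes had changed after 24 h. The globin sum was 61615 ± 8448 normalized counts (SD, n = 3), 8.03-fold below untreated cells. Among globins and erythroid membrane genes, 22 of 28 members fell and 0 rose (adjusted over the list alone, 0 rose and 22 fell). The median was -1.29 on the log2 scale (camera adjusted p = 2.12e-08, adjusted p = 0.27 with an estimated correlation). ERMAP, an erythroid membrane protein, went from 4530 ± 1210 to 430 ± 122 (-3.40, SE 0.26, adjusted p = 1.19e-06), and CTSE, cathepsin E, from 163 ± 67.4 to 13.8 ± 10.5 (-3.84, adjusted p = 0.00101, and -2.90 without 24 h replicate 1). In the heme biosynthesis list, 8 of 14 members fell and 0 rose (adjusted over the list alone, 0 rose and 8 fell). The median was -0.70 on the log2 scale (camera adjusted p = 0.00375, adjusted p = 0.417 with an estimated correlation). The largest rises included MLPH, a melanosome transport protein, from 2.66 ± 2.1 to 173 ± 16.4 (5.72, SE 0.38, adjusted p = 3.69e-07), and TJP3, a tight junction scaffold, from 10.1 ± 9.91 to 210 ± 4.53 (4.61, adjusted p = 4.38e-06, and 5.30 without untreated replicate 3). ALOX5, arachidonate 5-lipoxygenase, was listed at 0 in all 3 untreated libraries and at 14.7, 206 and 181 at 24 h, and its call was lost without 24 h replicate 2 (5.74) or 3 (5.83). In the granulocyte and monocyte list, 8 of 11 members rose and 0 fell (adjusted over the list alone, 8 rose and 0 fell). The median was 1.60 on the log2 scale (camera adjusted p = 0.000431, adjusted p = 0.24 with an estimated correlation). CSF3R, the receptor of granulocyte colony-stimulating factor, rose by 3.00 on the log2 scale (adjusted p = 2.44e-06).

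The integrated stress response list rose at 24 h, where 22 of 24 members rose and 0 fell (adjusted over the list alone, 22 rose and 0 fell). The median was 1.44 on the log2 scale (camera adjusted p = 4.09e-12, adjusted p = 0.239 with an estimated correlation). DDIT4 was at 21000 ± 4510 (3.17, SE 0.21, adjusted p = 4.43e-07). ALDH1L2, a mitochondrial folate enzyme, went from 244 ± 11.6 to 1800 ± 289 (2.87, adjusted p = 1.87e-08). DDIT3, the transcription factor CHOP, went from 913 ± 60.9 to 2610 ± 771 (1.48, adjusted p = 8.39e-06), and VLDLR, a lipoprotein receptor, from 7.43 ± 4.17 to 190 ± 24.5 (4.64, adjusted p = 1.57e-06). Sterol synthesis genes rose as a group. In the cholesterol biosynthesis and uptake list, 18 of 25 members rose and 1 fell (adjusted over the list alone, 18 rose and 1 fell). The median was 0.68 on the log2 scale (camera adjusted p = 6.63e-06, adjusted p = 0.379 with an estimated correlation). INSIG1, a sterol sensor of the endoplasmic reticulum, went from 2370 ± 64.5 to 6730 ± 777 (a rise of 1.5 on the log2 scale, adjusted p = 3.9e-06), and MSMO1, a sterol demethylase, from 970 ± 15.4 to 3360 ± 586 (1.78, adjusted p = 1.9e-06). In the fatty acid synthesis list, 6 of 16 members rose and 1 fell (adjusted over the list alone, 6 rose and 1 fell). The median was 0.37 on the log2 scale (camera adjusted p = 0.0453, adjusted p = 0.517 with an estimated correlation). ACSS2, an acetyl-CoA synthetase, went from 924 ± 118 to 4150 ± 630 (2.16, adjusted p = 1.8e-07).

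Growth-related lists were lower at 24 h than in untreated cells. Among MYC and ribosome biogenesis genes, 26 of 28 members fell and 0 rose (adjusted over the list alone, 0 rose and 27 fell). The median was -0.94 on the log2 scale (camera adjusted p = 1.1e-12, adjusted p = 0.318 with an estimated correlation). UTP20, a processome component, went from 4300 ± 88.7 to 1290 ± 216 (-1.75, adjusted p = 1.02e-06). In the DNA replication and G1/S list, 26 of 28 members fell and 0 rose (adjusted over the list alone, 0 rose and 26 fell). The median was -0.78 on the log2 scale (camera adjusted p = 6.43e-10, adjusted p = 0.27 with an estimated correlation). GINS3, a part of the replicative helicase, fell by 1.38 on the log2 scale (adjusted p = 7.56e-06). In the mitosis and G2/M list, 25 of 28 members fell and 1 rose (adjusted over the list alone, 1 rose and 26 fell). The median was -0.66 on the log2 scale (camera adjusted p = 5.96e-09, adjusted p = 0.318 with an estimated correlation). PLK1, a mitotic kinase, went from 8670 ± 820 to 3690 ± 547 (-1.24, adjusted p = 3.81e-06). In the DNA repair list, 13 of 29 members fell and 1 rose (adjusted over the list alone, 1 rose and 13 fell). The median was -0.23 on the log2 scale (camera adjusted p = 0.014, adjusted p = 0.335 with an estimated correlation). XRCC2 fell by 1.04 on the log2 scale (adjusted p = 7.59e-05). Among CDK inhibitors and cyclins D, 7 of 12 members rose and 2 fell (adjusted over the list alone, 7 rose and 2 fell). The median was 0.80 on the log2 scale (camera adjusted p = 0.0298, adjusted p = 0.379 with an estimated correlation). CDKN1A, which encodes the CDK inhibitor p21, went from 259 ± 30.6 to 606 ± 54.4 (1.22, adjusted p = 0.000114).

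In the heat shock list, 14 of 20 members fell and 1 rose (adjusted over the list alone, 1 rose and 14 fell). The median was -0.81 on the log2 scale (camera adjusted p = 3.46e-05, adjusted p = 0.327 with an estimated correlation). HSPA8 was at 29200 ± 8400 (-2.14, adjusted p = 1.57e-06). Among ER chaperones and unfolded protein response genes, 11 of 22 members fell and 4 rose (adjusted over the list alone, 4 rose and 11 fell). The median was -0.39 on the log2 scale (camera adjusted p = 0.0461, adjusted p = 0.566 with an estimated correlation). CALR, calreticulin, fell by 0.93 on the log2 scale (adjusted p = 9.16e-07), and EDEM1, which acts in the disposal of misfolded proteins, rose by 1.43 (adjusted p = 6.93e-06). In the NRF2 list, 12 of 24 members fell and 1 rose (adjusted over the list alone, 1 rose and 14 fell). The median was -0.29 on the log2 scale (camera adjusted p = 0.014, adjusted p = 0.417 with an estimated correlation). SRXN1, sulfiredoxin, fell by 1.12 on the log2 scale (adjusted p = 5.1e-05). In the p53 target list, 9 of 21 members rose and 3 fell (adjusted over the list alone, 10 rose and 3 fell). The median was 0.25 on the log2 scale (camera adjusted p = 0.0202, adjusted p = 0.379 with an estimated correlation). TP53INP1 went from 134 ± 8.46 to 870 ± 128 (2.68, adjusted p = 6.46e-06), while AEN, an exonuclease, fell by 1.37 on the log2 scale (adjusted p = 3.14e-06). Among apoptosis regulators, 10 of 26 members rose and 3 fell (adjusted over the list alone, 10 rose and 3 fell). The median was 0.37 on the log2 scale (camera adjusted p = 0.0453, adjusted p = 0.417 with an estimated correlation). BBC3, which encodes the BH3-only protein PUMA, went from 354 ± 15.4 to 1120 ± 206 (1.64, adjusted p = 8.22e-06). In the interferon-stimulated list, 10 of 15 members rose and 0 fell (adjusted over the list alone, 10 rose and 0 fell). The median was 0.82 on the log2 scale (camera adjusted p = 0.00287, adjusted p = 0.239 with an estimated correlation). IFITM3 rose by 1.20 on the log2 scale (adjusted p = 3e-06). Among nuclear OXPHOS subunits, 15 of 32 members fell and 1 rose (adjusted over the list alone, 1 rose and 15 fell). The median was -0.20 on the log2 scale (camera adjusted p = 0.0097, adjusted p = 0.566 with an estimated correlation). TFAM, a mitochondrial transcription factor that is in the list but is not itself a subunit, fell by 1.12 on the log2 scale (adjusted p = 3.67e-05).

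At 24 h, 7343 of 15424 tested genes changed by the limma test, of which 3530 rose and 3813 fell, and among them 1794 rose and 841 fell by 2-fold or more. Changes of that size were 2320 up and 524 down with equal totals, 1475 and 1222 with median centring and 1330 and 1126 with quantile normalization. For all calls, with equal totals the split was 4761 up and 2657 down, with the median of all tested genes at 0.20 instead of 0.02. With median centring it was 2839 up and 4772 down, with that median at -0.12. Quantile normalization ended the calls of the NRF2 (-0.16), DNA repair (-0.11) and ER chaperone (-0.27) lists and gave the OXPHOS list a median of 0.04, and equal totals ended those of the OXPHOS (-0.01) and ER chaperone (-0.21) lists. A required mean of at least 50 left 13 of the 18 calls and ended those of the apoptosis (0.30), ER chaperone (-0.37), NRF2 (-0.29), fatty acid (0.36) and DNA repair (-0.23) lists. Ranks left 14, without the CDK inhibitor (0.80), apoptosis (0.37), ER chaperone (-0.39) and fatty acid (0.37) lists. Removing the length and GC trend, chosen after the data were seen, ended the ER chaperone (-0.36) and fatty acid (0.38) calls. The apoptosis call was lost with median centring (0.23) and without untreated replicate 1 (0.35) or 2 (0.32) or 24 h replicate 3 (0.29). The fatty acid call was lost with median centring (0.23), with a fit of the 2 groups alone (0.37) and without untreated replicate 1 (0.28) or 2 (0.36), 24 h replicate 1 (0.31) or 3 (0.29) or 48 h replicate 1 (0.37). The ER chaperone call was lost without untreated replicate 3 (-0.34), 24 h replicate 2 (-0.37) or 48 h replicate 1 (-0.39), and that of the CDK inhibitors and cyclins D without 24 h replicate 2 (0.86).

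The comparison at 48 h asked the same of the longest exposure. MYC, the growth-promoting transcription factor (ENSG00000136997, GRCh38 chromosome 8, 127735434 to 127741434), went from 18000 ± 409 to 1150 ± 186 normalized counts (SD, n = 3; -3.98, SE 0.19, adjusted p = 3.3e-09), after 11500 ± 2720 at 8 h and 8870 ± 2350 at 24 h. CYP1A1, a xenobiotic-metabolizing cytochrome P450 (ENSG00000140465, GRCh38 chromosome 15, 74719542 to 74725610), went from 92.5 ± 10.7 to 5220 ± 1560 (5.76, SE 0.24, adjusted p = 1.48e-09), after 953 ± 241 at 8 h and 1850 ± 478 at 24 h. NGFR, the low-affinity neurotrophin receptor, went from 5.42 ± 5.25 to 319 ± 51.1 (5.94, adjusted p = 1.17e-06, and 6.57 without untreated replicate 2), and MLPH reached 385 ± 61.5 (6.86, adjusted p = 7.19e-09). NBPF6 went from 241 ± 11.8 to 2.89 ± 1.47 (-6.04, adjusted p = 2.02e-07). RGL2, SLC39A4, TEX15, RNH1, MINAR1 and CILK1 were listed at 0 in all 3 libraries of 48 h. Since RPS9, a ribosomal protein gene of every cell, was listed at 0 in 7 of 12 libraries, such a 0 is not read as absence.

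Cytosolic ribosomal protein genes rose at 48 h, where 29 of 32 members rose and 1 fell (adjusted over the list alone, 29 rose and 1 fell). The median was 1.11 on the log2 scale (camera adjusted p = 6.43e-10, adjusted p = 0.417 with an estimated correlation). With quantile normalization that median was 0.61. RPL3 went from 64700 ± 1450 to 193000 ± 19300 (1.58, SE 0.09, adjusted p = 1.41e-08), and RPL11 from 30600 ± 1480 to 85300 ± 8010 (1.48, adjusted p = 6e-09). The list of MYC and ribosome biogenesis genes, most of which act in the nucleolus, moved the other way: 26 of 28 members fell and 2 rose (adjusted over the list alone, 2 rose and 26 fell). The median was -1.24 on the log2 scale (camera adjusted p = 6.96e-09, adjusted p = 0.379 with an estimated correlation). TFB2M, a mitochondrial transcription factor, went from 3860 ± 227 to 470 ± 11.5 (-3.04, adjusted p = 7.72e-10). In the DNA replication and G1/S list, 25 of 28 members fell and 2 rose (adjusted over the list alone, 2 rose and 26 fell). The median was -1.01 on the log2 scale (camera adjusted p = 1.34e-06, adjusted p = 0.335 with an estimated correlation). PCNA, the sliding clamp of DNA polymerases, went from 9090 ± 89.1 to 1910 ± 311 (-2.27, adjusted p = 2.39e-09). In the mitosis and G2/M list, 18 of 28 members fell and 2 rose (adjusted over the list alone, 2 rose and 18 fell). The median was -0.44 on the log2 scale (camera adjusted p = 0.00106, adjusted p = 0.47 with an estimated correlation). CCNF, cyclin F, fell by 2.72 on the log2 scale (adjusted p = 8.28e-09), and ASPM, a spindle protein, fell by 2.24 (adjusted p = 2.08e-09).

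The globin sum at 48 h was 108003 ± 3554 normalized counts (SD, n = 3), 4.58-fold below untreated cells. Among globins and erythroid membrane genes, 19 of 28 members fell and 1 rose (adjusted over the list alone, 1 rose and 19 fell). The median was -1.40 on the log2 scale (camera adjusted p = 0.000767, adjusted p = 0.417 with an estimated correlation). SLC4A1 was at 10 ± 6.55 (-4.90, adjusted p = 1.56e-05, and -5.57 without untreated replicate 3). In the granulocyte and monocyte list, 8 of 11 members rose and 1 fell (adjusted over the list alone, 8 rose and 1 fell). The median was 2.83 on the log2 scale (camera adjusted p = 0.00392, adjusted p = 0.27 with an estimated correlation). ITGAM, the integrin alpha M of myeloid cells, went from 37.6 ± 21.2 to 483 ± 211 (3.67, adjusted p = 4.66e-06). In the integrated stress response list, 16 of 24 members rose and 3 fell (adjusted over the list alone, 16 rose and 3 fell). The median was 1.41 on the log2 scale (camera adjusted p = 0.000182, adjusted p = 0.368 with an estimated correlation). GDF15, a stress-induced cytokine, went from 1890 ± 230 to 19700 ± 1220 (3.39, adjusted p = 3.17e-08), and CTH, an enzyme of cysteine synthesis, from 385 ± 32.3 to 2760 ± 141 (2.84, adjusted p = 1.67e-09). In the interferon-stimulated list, 8 of 15 members rose and 2 fell (adjusted over the list alone, 8 rose and 2 fell). The median was 0.85 on the log2 scale (camera adjusted p = 0.0344, adjusted p = 0.27 with an estimated correlation). IRF1, a transcription factor of the interferon response, went from 646 ± 134 to 3060 ± 360 (2.26, adjusted p = 1.72e-07). In the cholesterol list, 14 of 25 members rose and 4 fell (adjusted over the list alone, 14 rose and 5 fell). The median was 0.57 on the log2 scale (camera adjusted p = 0.0285, adjusted p = 0.612 with an estimated correlation). FDFT1, squalene synthase, went from 346 ± 38.7 to 3670 ± 552 (3.40, adjusted p = 5.27e-09), whereas LSS, lanosterol synthase, fell from 1560 ± 289 to 331 ± 75.3 (-2.24, adjusted p = 1.31e-06). In the autophagy and lysosome list, 16 of 30 members rose and 6 fell (adjusted over the list alone, 16 rose and 6 fell). The median was 0.40 on the log2 scale (camera adjusted p = 0.0461, adjusted p = 0.385 with an estimated correlation). WIPI1, an autophagosome protein, went from 145 ± 8.52 to 899 ± 66.8 (2.62, adjusted p = 1.49e-08).

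At 48 h, 10207 of 15424 tested genes changed by the limma test, of which 4989 rose and 5218 fell, and among them 2759 rose and 3166 fell by 2-fold or more. With equal totals the split was 4146 up and 6154 down, with the median of all tested genes at -0.24 instead of -0.05. The autophagy call was lost with equal totals (0.21), with quantile normalization (0.38), with a required mean of at least 50 (0.42), with a fit of the 2 groups alone (0.40), and without untreated replicate 2 (0.37), 24 h replicate 1 or 2 (0.40) or 48 h replicate 1 (0.41) or 2 (0.38). That of the cholesterol list was lost with the same required mean (0.57).

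**Figure D2:**
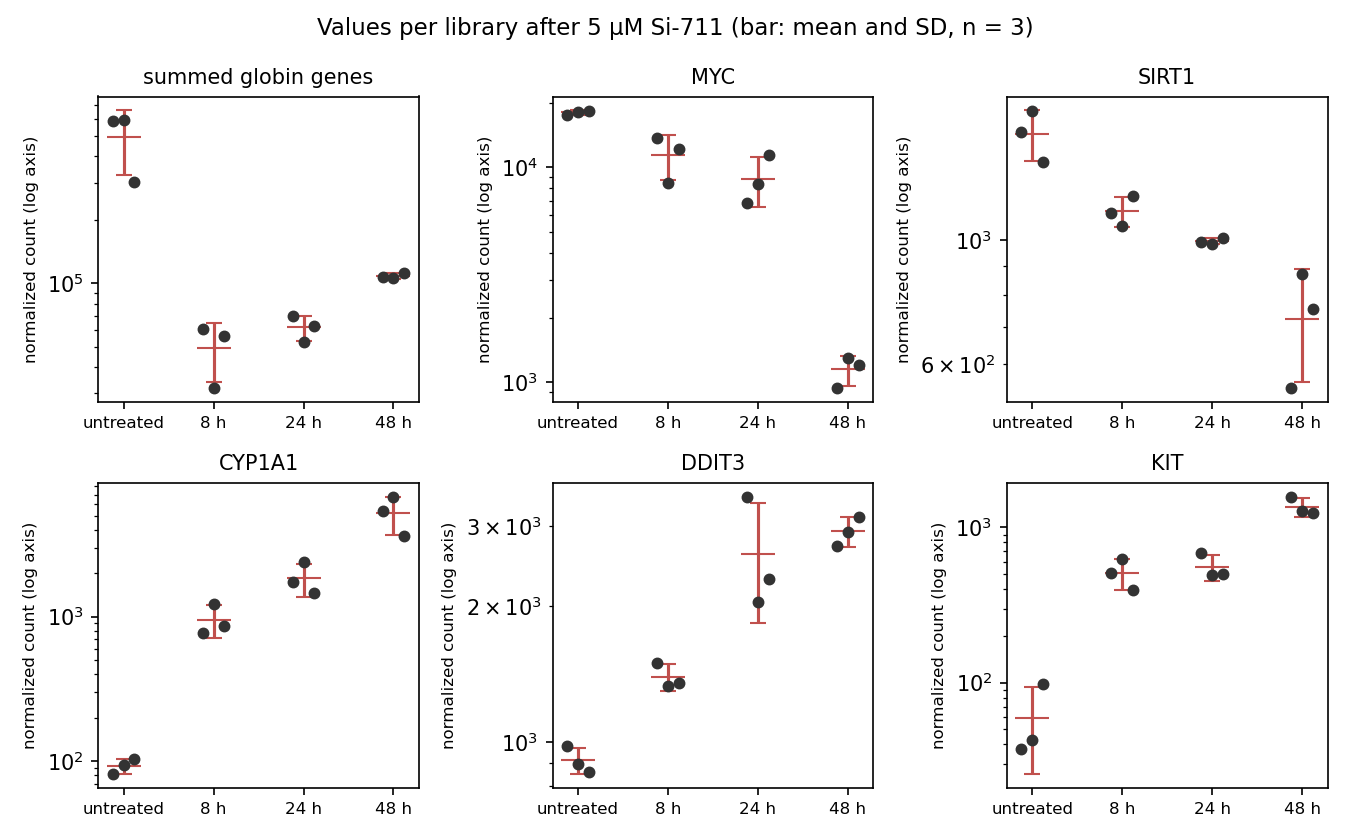
Normalized counts per library on a log axis for the globin sum, MYC, SIRT1, CYP1A1, DDIT3 and KIT in untreated cells and after 8, 24 and 48 h of 5 µM Si-711, with points for libraries and red bars for the mean and SD (n = 3). The highest 8 h library of the globin sum, 60743, lies below the lowest untreated one, 301565.

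Some lists were called at certain times and not at others. At 8 h, the p53 targets (6 of 21 members rose and 2 fell (adjusted over the list alone, 7 rose and 2 fell; camera adjusted p = 0.0761)), ER chaperones (10 of 22 members fell and 1 rose (adjusted over the list alone, 2 rose and 10 fell; camera adjusted p = 0.0971)), cholesterol genes (6 of 25 members fell and 3 rose (adjusted over the list alone, 3 rose and 10 fell; camera adjusted p = 0.38)), fatty acid genes (5 of 16 members rose and 5 fell (adjusted over the list alone, 5 rose and 5 fell; camera adjusted p = 0.921)), DNA repair genes (7 of 29 members fell and 1 rose (adjusted over the list alone, 1 rose and 7 fell; camera adjusted p = 0.0685)) and autophagy genes (5 of 30 members rose and 5 fell (adjusted over the list alone, 5 rose and 7 fell; camera adjusted p = 0.912)) were not called. At 24 h, the megakaryocyte (3 of 11 members rose and 1 fell (adjusted over the list alone, 3 rose and 1 fell; camera adjusted p = 0.227)), lymphocyte (2 of 6 members rose and 0 fell (adjusted over the list alone, 2 rose and 0 fell; camera adjusted p = 0.12)), NF-kB (8 of 18 members rose and 2 fell (adjusted over the list alone, 8 rose and 2 fell; camera adjusted p = 0.106)), ribosomal protein (3 of 32 members rose and 2 fell (adjusted over the list alone, 3 rose and 2 fell; camera adjusted p = 0.76)) and autophagy (7 of 30 members rose and 8 fell (adjusted over the list alone, 7 rose and 8 fell; camera adjusted p = 0.971)) lists were not called. The ribosomal protein list at 24 h was called upward with equal totals (0.21) and quantile normalization (0.35). At 48 h, the heme (8 of 14 members fell and 3 rose (adjusted over the list alone, 3 rose and 8 fell; camera adjusted p = 0.0813)), CDK inhibitor (8 of 12 members rose and 3 fell (adjusted over the list alone, 8 rose and 3 fell; camera adjusted p = 0.149)), megakaryocyte (4 of 11 members rose and 3 fell (adjusted over the list alone, 4 rose and 3 fell; camera adjusted p = 0.921)) and lymphocyte (3 of 6 members rose and 1 fell (adjusted over the list alone, 3 rose and 1 fell; camera adjusted p = 0.511)) lists were not called, and neither were the heat shock (9 of 20 members rose and 9 fell (adjusted over the list alone, 9 rose and 9 fell; camera adjusted p = 0.935)), NRF2 (8 of 24 members rose and 8 fell (adjusted over the list alone, 9 rose and 8 fell; camera adjusted p = 0.971)) and NF-kB (6 of 18 members rose and 2 fell (adjusted over the list alone, 5 rose and 2 fell; camera adjusted p = 0.553)) lists. The apoptosis (12 of 26 members rose and 7 fell (adjusted over the list alone, 12 rose and 7 fell; camera adjusted p = 0.312)), p53 (10 of 21 members rose and 6 fell (adjusted over the list alone, 10 rose and 6 fell; camera adjusted p = 0.288)), ER chaperone (8 of 22 members fell and 4 rose (adjusted over the list alone, 4 rose and 8 fell; camera adjusted p = 0.574)), fatty acid (7 of 16 members rose and 3 fell (adjusted over the list alone, 7 rose and 3 fell; camera adjusted p = 0.13)), DNA repair (17 of 29 members fell and 7 rose (adjusted over the list alone, 7 rose and 17 fell; camera adjusted p = 0.259)) and OXPHOS (18 of 32 members rose and 8 fell (adjusted over the list alone, 18 rose and 8 fell; camera adjusted p = 0.121)) lists were not called at 48 h either. The heme list passed at 48 h without untreated replicate 3 (-0.64), and the OXPHOS list without 48 h replicate 2 (0.42). At 8 h, the ER chaperone list passed without 8 h replicate 3 (-0.20) and the DNA repair list without untreated replicate 3 (-0.21), with median centring (-0.28) and with a fit of the 2 groups alone (-0.19). With no filter on low values, the p53 (0.17), ER chaperone (-0.20) and DNA repair (-0.19) lists passed at 8 h. At 48 h the CDK inhibitor (0.42), heme (-0.59), OXPHOS (0.35) and fatty acid (0.32) lists passed in that setting. The tests of the successive times, not these calls, bear on whether times differed.

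Further lists were not called at any time. For NAD metabolism genes, 6, 7 and 9 of 15 members rose and 1, 3 and 2 fell at 8, 24 and 48 h (adjusted over the list alone, 6, 7 and 9 rose and 4, 3 and 2 fell), with camera adjusted p = 0.491, 0.331 and 0.231. NMRK1, a nicotinamide riboside kinase, rose by 2.33 on the log2 scale at 24 h (adjusted p = 0.000285), and PARP1, an NAD-consuming polymerase, fell by 1.99 at 48 h (adjusted p = 1.48e-09). Among lysine deacetylases and acetyltransferases, 2, 5 and 9 of 20 members rose and 4, 8 and 6 fell at 8, 24 and 48 h (adjusted over the list alone, 4, 5 and 9 rose and 6, 8 and 6 fell), with camera adjusted p = 0.828, 0.56 and 0.45. EP300, an acetyltransferase, fell by 2.24 at 48 h (adjusted p = 3.94e-06), and HDAC6, a tubulin deacetylase, rose by 1.71 (adjusted p = 1.51e-06). Among erythroid and megakaryocytic transcription factors, 4, 5 and 6 of 14 members rose and 5, 6 and 6 fell at 8, 24 and 48 h (adjusted over the list alone, 4, 5 and 6 rose and 5, 6 and 6 fell), with camera adjusted p = 0.867, 0.828 and 0.921. KLF1, an activator of erythroid genes, fell by 2.35 at 48 h (adjusted p = 6.4e-07), and TAL1 fell by 2.72 (adjusted p = 1.7e-08). For FOXO targets, 5, 8 and 10 of 26 members rose and 6, 7 and 8 fell at 8, 24 and 48 h (adjusted over the list alone, 5, 10 and 10 rose and 7, 7 and 8 fell), with camera adjusted p = 0.779, 0.582 and 0.616. For ERK and immediate early genes, 7, 8 and 7 of 24 members rose and 4, 5 and 11 fell at 8, 24 and 48 h (adjusted over the list alone, 7, 9 and 7 rose and 4, 5 and 11 fell), with camera adjusted p = 0.521, 0.312 and 0.288. FOSL1 fell by 3.47 at 48 h (adjusted p = 6.4e-09), and JUN rose by 3.37 (adjusted p = 2.58e-08). For BCR-ABL1 and STAT5 targets, 8, 8 and 5 of 20 members rose and 5, 6 and 11 fell at 8, 24 and 48 h (adjusted over the list alone, 9, 8 and 5 rose and 6, 6 and 11 fell), with camera adjusted p = 0.172, 0.308 and 0.231. This list passed at 8 h (0.35) and 24 h (0.43) with quantile normalization. SOCS3 fell by 4.40 at 48 h (adjusted p = 6.39e-09), and PIM1, a kinase, rose by 2.61 (adjusted p = 5.33e-09).

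For mitochondrially encoded genes, 1, 3 and 5 of 13 members rose and 2, 6 and 5 fell at 8, 24 and 48 h (adjusted over the list alone, 1, 3 and 5 rose and 2, 6 and 6 fell), with camera adjusted p = 0.714, 0.701 and 0.917. MT-CO1 rose at 24 h by 0.90 on the log2 scale (adjusted p = 0.000208) but was at -0.22 with quantile normalization. That setting put its change at 0 at both 8 and 48 h. It gives the top-ranked gene of each library the same value, so it may be unable to show a rise of MT-CO1. Among glycolysis and hypoxia genes, 7, 7 and 11 of 27 members rose and 6, 12 and 12 fell at 8, 24 and 48 h (adjusted over the list alone, 7, 8 and 11 rose and 6, 12 and 12 fell), with camera adjusted p = 0.935, 0.45 and 0.921. SLC2A1, a glucose transporter, fell by 2.86 at 48 h (adjusted p = 1.95e-07). For LXR targets, 0, 1 and 4 of 10 members rose and 3, 2 and 3 fell at 8, 24 and 48 h (adjusted over the list alone, 0, 1 and 4 rose and 3, 2 and 3 fell), with camera adjusted p = 0.25, 0.901 and 0.921. Among tubulins and tubulin folding genes, 3, 5 and 10 of 21 members rose and 8, 12 and 9 fell at 8, 24 and 48 h (adjusted over the list alone, 4, 5 and 10 rose and 9, 12 and 9 fell), with camera adjusted p = 0.0602, 0.125 and 0.993. The tubulin list passed at 8 h without untreated replicate 1 (-0.15) or 8 h replicate 1 (-0.25), with no filter on low values (-0.18) and with the length and GC trend removed (-0.17), a setting chosen after the data were seen. It passed at 24 h with no filter (-0.40). TUBB2B rose by 3.99 at 48 h (adjusted p = 6e-09), and TUBB4B fell by 2.26 (adjusted p = 2.3e-10). For ABC drug transporters, 0, 3 and 3 of 10 members rose and 1, 4 and 5 fell at 8, 24 and 48 h (adjusted over the list alone, 0, 3 and 3 rose and 1, 4 and 5 fell), with camera adjusted p = 0.971, 0.971 and 0.779. ABCG2 fell by 2.00 at 48 h (adjusted p = 2.14e-05). Among core clock genes, 1, 3 and 8 of 15 members rose and 1, 2 and 2 fell at 8, 24 and 48 h (adjusted over the list alone, 1, 3 and 8 rose and 1, 2 and 2 fell), with camera adjusted p = 0.993, 0.971 and 0.105. DBP rose by 2.78 at 48 h (adjusted p = 1.35e-06). In the stromal and epithelial check list, 1 of 8 members rose at 24 h and 2 fell, and 2 rose and 1 fell at 48 h, with the same numbers adjusted over the list alone (camera adjusted p = 0.723 and 0.912). FN1, fibronectin, rose by 3.29 at 8 h (adjusted p = 4.04e-05).

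Of 37 lists, 17 were called at 8 h (8 up and 9 down), 18 at 24 h (8 up and 10 down) and 10 at 48 h (6 up and 4 down) by camera with a preset correlation. With an estimated correlation 0 were called at each time, although 7, 7 and 2 had an unadjusted p under 0.05. With fry, 23, 26 and 27 were called, which asks whether the members move on balance one way without comparing them with other genes. Median, mean and test differed in sign for none of the called lists. Among the others they did so for the heat shock list at 48 h, with a median of -0.01, a mean of 0.27 and a downward test, and for the NRF2 list at 48 h, with a median of 0.08, a mean of -0.18 and a downward test. They also did so for erythroid transcription factors and ABC transporters at each time, stromal genes and autophagy genes at 8 and 24 h, and glycolysis genes at 8 and 48 h. The same held for FOXO targets and fatty acid genes at 8 h, ribosomal proteins and clock genes at 24 h, and megakaryocyte, mitochondrially encoded, LXR and tubulin genes at 48 h.

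**Figure D3:**
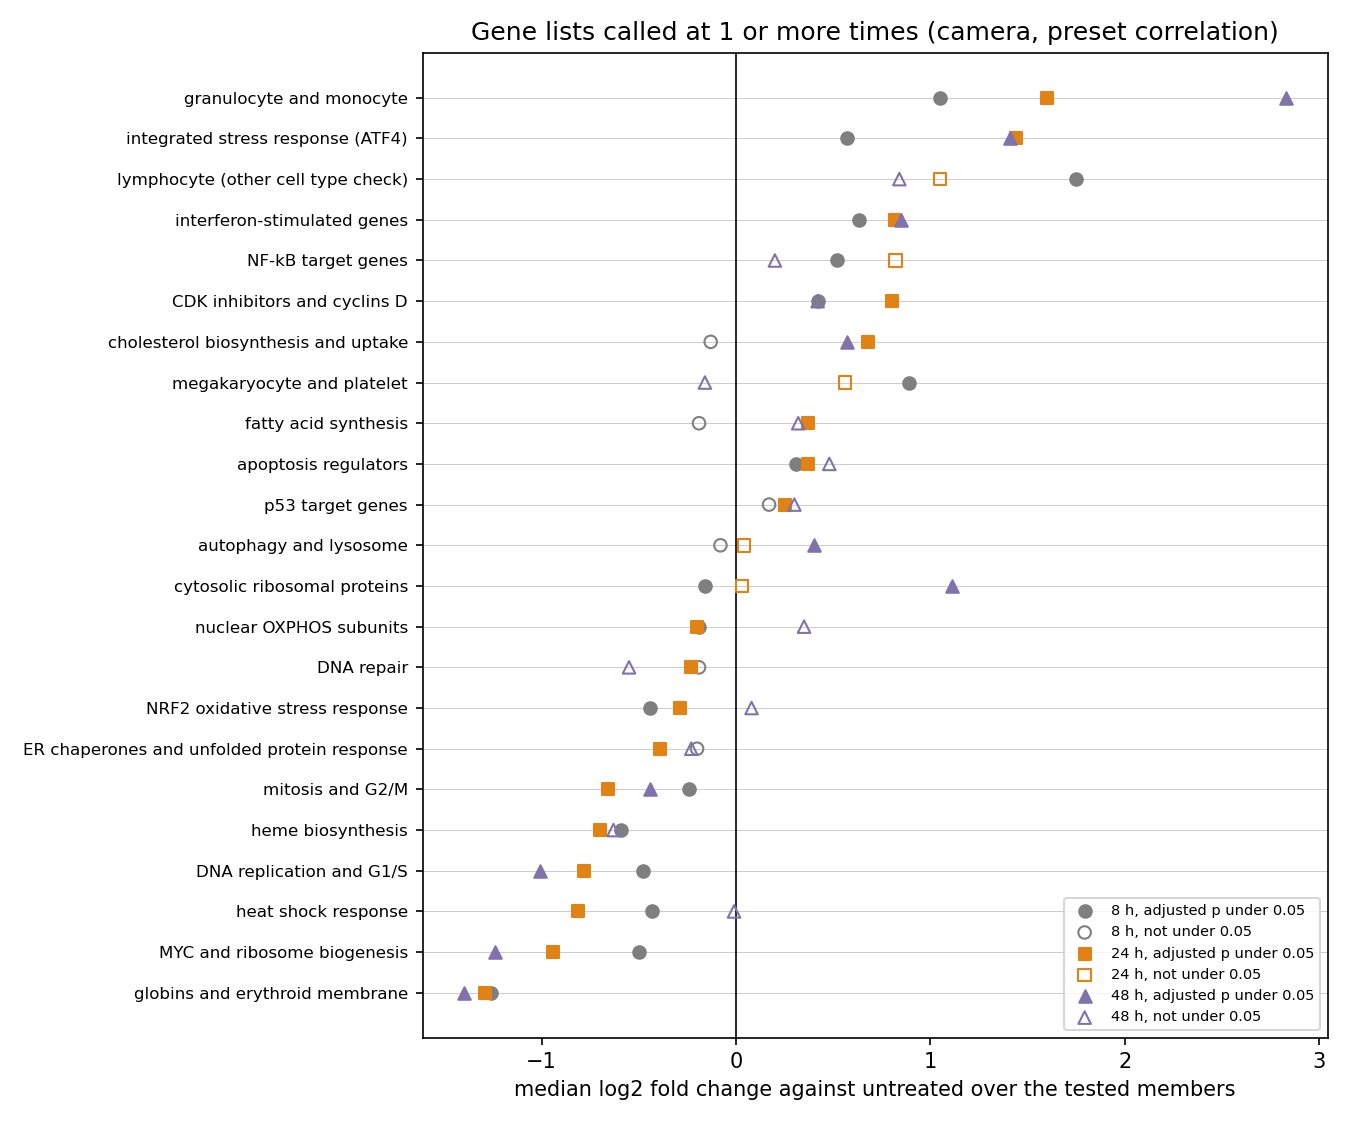
Median log2 fold change against untreated of the tested members of each gene list called at 1 or more times, with 1 symbol per time, filled where the camera adjusted p is under 0.05 and open where it is not. The ribosomal protein list lies at -0.16, 0.03 and 1.11 at 8, 24 and 48 h, and the 8 h and 24 h medians of this list turn to 0.13 and 0.35 with quantile normalization.

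Successive times were compared to ask what changed between them. From 8 to 24 h, ASS1, argininosuccinate synthase, rose from 673 ± 113 to 3480 ± 519 normalized counts (SD, n = 3; 2.37, SE 0.15, adjusted p = 1.04e-05), and MLPH rose by 2.61 on the log2 scale (adjusted p = 0.00101). In the cholesterol list, 20 of 25 members rose and 1 fell between these times (camera adjusted p = 9.87e-16, adjusted p = 0.416 with an estimated correlation). In the integrated stress response list, 14 of 24 members rose and 0 fell (camera adjusted p = 7.85e-12, adjusted p = 0.416 with an estimated correlation). In the mitosis list, 17 of 28 members fell and 0 rose (camera adjusted p = 2.24e-11, adjusted p = 0.444 with an estimated correlation). Each of the 5 largest falls under the rule for named genes either had libraries listed at 0 or lost its call when single libraries were left out, so no fold is given for them. In all, 2798 of 15424 genes changed by the limma test, 1282 up and 1516 down. The count was 1397 without 8 h replicate 3, 1622 without 8 h replicate 1 and 1415 without 24 h replicate 1. It was 1022 up and 1917 down with median centring.

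From 24 to 48 h, HSPA1A, a heat-inducible HSP70, rose from 38 ± 8.45 to 2340 ± 234 normalized counts (SD, n = 3; 5.92, SE 0.53, adjusted p = 1.45e-06). HSPA1B, its near-identical neighbor, was listed at 0, 67.4 and 11.2 at 24 h and at 1260, 1150 and 1360 at 48 h, and reads can be divided unevenly between the pair. PAN3-AS1, an antisense transcript, fell from 114 ± 2.27 to 1.83 ± 0.751 (-5.38, adjusted p = 8.51e-08). In the ribosomal protein list, 30 of 32 members rose and 0 fell (camera adjusted p = 2.82e-15, adjusted p = 0.481 with an estimated correlation). In the OXPHOS list, 23 of 32 members rose and 3 fell (camera adjusted p = 4.35e-05, adjusted p = 0.524 with an estimated correlation). The heat shock list, with 11 of 20 up and 4 down, rose as well (camera adjusted p = 0.00425, adjusted p = 0.524 with an estimated correlation). In all, 8058 of 15424 genes changed by the limma test, 3874 up and 4184 down. With equal totals the split was 1829 up and 6607 down, with the median of all tested genes at -0.43 instead of -0.06, and with median centring it was 5174 up and 3239 down, with that median at 0.13.

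Over the whole course, 11621 of 15424 genes (75.3%) changed by limma's moderated F-test. Across the 3 comparisons with untreated cells, 1408 genes rose at each time and 1419 fell at each time, and 3913 were called at 48 h alone of the 3 times. The calls at 8 and 24 h shared 3751 genes in the same direction and 13 in opposite directions. With independent calls 458 shared rises and 580 shared falls would arise, against 1758 and 1993 found. For 24 and 48 h, 5483 genes moved in the same direction and 459 in opposite directions, and for 8 and 48 h 2946 and 488. All 3 comparisons used the same untreated libraries, which alone gave a correlation of 0.5 across genes in simulations of unchanged groups. The measured correlations across genes were 0.76 for 8 and 24 h, 0.46 for 8 and 48 h and 0.68 for 24 and 48 h. The covariances were 0.618, 0.549 and 1.039, against 0.094, 0.093 and 0.094 in the simulations, where 0 calls were shared in 20 simulations. Because no gene was changed in them, few calls could arise at all. That 0 therefore does not measure how many shared calls the untreated libraries add. The part of the shared calls owed to the shared untreated libraries was not separated, since 3 libraries do not make separate sets of 2 or more.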

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

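The tests of reads moved between globin genes, of the spread between untreated cultures, of time in culture, of low depth and of the share of genes in the major histocompatibility complex were chosen only after the results were seen, as were the removal of the length and GC trend and the omission of 2 sets of genes.

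The lists below were called in a camera test of the difference between successive times with a preset correlation. With an estimated correlation their adjusted p lay between 0.416 and 0.855, and none was called. From 8 to 24 h the cholesterol list changed by a median of 0.80 on the log2 scale (camera adjusted p = 9.87e-16), from -0.13 to 0.68 against untreated cells. The integrated stress response list changed by 0.55 (7.85e-12) and the fatty acid list by 0.41 (4.35e-05). The MYC and ribosome biogenesis list changed by -0.48 (2.75e-12), the mitosis list by -0.42 (2.24e-11), the heat shock list by -0.38 (0.000118) and the DNA replication list by -0.30 (4.35e-05). The ribosomal protein list changed by 0.19 (0.000328). From 24 to 48 h the ribosomal protein list changed by 1.06 (2.82e-15), the OXPHOS list by 0.43 (4.35e-05), the heat shock list by 0.55 (0.00425), the autophagy list by 0.51 (0.00276) and the clock list by 0.70 (0.027). The ERK list changed by -0.80 (0.0139), with 10 of 24 members falling, and the BCR-ABL1 and STAT5 list by -0.74 (0.00585), with 12 of 20 falling.

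Single genes changed between successive times and were called on opposite sides of untreated cells at the 2 times. ACAT2, a thiolase of sterol synthesis, rose by 0.97 from 8 to 24 h (limma adjusted p = 0.000517), from -0.54 to 0.43 against untreated cells. From 24 to 48 h, HSPA1A rose by 5.92 (adjusted p = 1.45e-06), from -1.86 to 4.07. Another heat shock gene, DNAJB1, rose by 2.23 (adjusted p = 8.32e-08), from -1.24 to 0.98. AKR1C2, an aldo-keto reductase, rose by 0.83 (adjusted p = 7.5e-05), and KRT18, a keratin, rose by 0.74 (adjusted p = 0.000144), from -0.43 to 0.32. Both calls of KRT18 against untreated cells were lost with equal totals (-0.24 and 0.12), that at 24 h also with quantile normalization (-0.13). Its call at 48 h ended too without untreated replicate 1 (0.26) or 2 (0.27) or 48 h replicate 1 (0.28) or 3 (0.26). F2RL3, the thrombin receptor PAR4, fell with a log2 fold change of -3.46 (adjusted p = 8.51e-08), from 0.70 to -2.77. Its call at 24 h was lost without untreated replicate 1 (0.57) or 24 h replicate 2 (0.61) or 3 (0.59). LSS, lanosterol synthase, fell with -2.92 (adjusted p = 4.51e-07), from 0.68 to -2.24, and DUSP5, an ERK phosphatase, with -1.78 (adjusted p = 2.99e-06), from 1.03 to -0.75.

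The fall of the globins at 8 h is weighed first. Exchange of reads between near-identical globin genes would leave their sum in place, but the log2 ratio of the summed values was -3.32. Library scaling was argued against by the highest median of the globins over 4 scalings, -2.98, and spread between untreated cultures by the highest 8 h library, which held 0.201 of the lowest untreated one. Time in culture or the vehicle stays open, because 0 untreated or vehicle libraries were collected at 8 h, and its effect cannot be told apart from that of the compound. An effect of Si-711 may account for the fall, as a hypothesis.

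The rise of cytosolic ribosomal protein genes at 48 h is the next pattern. Scaling lowered the median log2 fold change of the list from 1.11 to no less than 0.61, with quantile normalization. Removing a trend with transcript length and GC content, fitted on the other genes, left a median of 1.08 (SD 0.57 over the 32 members), where the trend held 2.45% of the variance. Of 22 tested non-ribosomal genes whose mRNAs begin with a 5 prime terminal oligopyrimidine tract, 17 rose and 2 fell (camera p = 8.18e-06, p = 0.0737 with an estimated correlation), in a test fixed before its values were seen, which is consistent with a rise shared by that mRNA class. A change in the stability of such mRNAs, time in culture and the compound stay open.

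A further set of genes switched between libraries of the same group, at under 1 in one and over 100 in another. They numbered 79 of 15424. In the groups where they did not switch the median over them was 107 reads (quartiles 37 and 280). A value over 100 was required to enter the set, so genes of low depth in every library were left out by the rule. The 107 reads are therefore no independent test of low depth. The share lying in the major histocompatibility complex was 25.3 times that of other tested genes (12 of 73 genes with a position, 16.4% against 0.651%), in line with reads shared between near-identical loci, such as haplotype copies, for these 12. Main transcripts missing from an older annotation stay open, with a share 2.63 times that of other genes but 2 of 64 genes behind it. No biological explanation was tested.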

How the results depend on the processing

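The settings that removed a length and GC trend or left out genes with switching values or late transcripts were chosen after seeing the data; the others were planned. Of 15600 values of single genes and lists under alternatives, 15113 kept direction and side of the threshold, 429 lost the call, 54 gained it and 4 reversed, all 4 with quantile normalization: RPL5 at 8 h (0.01), MT-CO1 at 24 h (-0.22), the ribosomal protein list at 8 h (0.13) and the OXPHOS list at 24 h (0.04). The reversal of MT-CO1 may be built into that setting, as described for this gene above. Most of the single genes had been picked for passing the main test, so a kept call is partly built in. Many runs also left out a library outside the comparison scored. These numbers therefore do not measure the stability of the tested genes at large. A threshold of 0.01 in place of 0.05, which by construction calls fewer, lowered the genes called at 8 h to 2366, those of 24 h against 8 h to 1007, the shared calls of 8 and 24 h to 2079 and of 8 and 48 h to 1686, and the lists called at 24 h to 11. Lists called fell to 0 at each time with an estimated correlation, and rose to 27 at 48 h with fry, which asks another question. Leaving out 1 library gave 1397 (without 8 h replicate 3) to 3144 (without 48 h replicate 2) genes for 24 h against 8 h, with 1622 without 8 h replicate 1 and 1415 without 24 h replicate 1; with 2 libraries left in an arm, fewer degrees of freedom are one part of that, and the rest of the cause was not tested. The counts of 8, 24 and 48 h against untreated, 24 h against 8 h and 48 h against 24 h were 4214, 7395, 10090, 2794 and 7771 without the length and GC trend, 4380, 7386, 10226, 2829 and 8079 without switching genes, and 4329, 7295, 10114, 2781 and 8005 without genes of late transcripts. With a replicate block they were 4554, 7515, 10286, 2975 and 8154, each above the main count. Residual correlations of libraries with the same number were -0.07 to 0.14, with 2 of 18 over 0.1. Those of libraries with other numbers were -0.16 to 0.11. Whether libraries of the same number shared a batch is not given in the sources used here and stays open. edgeR and DESeq2 were not run, as whole reads were not recovered. On simulated data 16.4% of 1.5-fold, 86.6% of 2-fold and 100% of 4-fold changes were found. The simulation changed 67, 67 and 66 of 15424 genes by these folds, whereas 4347 were called at 8 h. With more changed genes the adjusted threshold is easier to pass, so these shares hold for the simulated setting alone. How many small changes were missed with 3 libraries per group in the real comparisons was not measured.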

Other observations

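The 2 lists of this part that cover mast cells and receptor targets, and the genes named in them, were chosen after the largest rises had been seen, and their own values were examined only once the lists were fixed. KIT, PRG2, ACTB and RPS27 were singled out after their values were seen.

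Among the genes that rose at 8 h was KIT, the stem cell factor receptor (GRCh38 chromosome 4, 54657918 to 54740715), which went from 59.4 ± 33.7 normalized counts (SD, n = 3) in untreated cells to 512 ± 117 at 8 h, 557 ± 108 at 24 h and 1360 ± 188 at 48 h (log2 fold changes 3.20, 3.33 and 4.63, limma adjusted p = 1.9e-05, 3.08e-06 and 2.84e-08). PRG2, an eosinophil and basophil granule protein, went from 346 to 3080 at 8 h (3.08, adjusted p = 8.83e-05), and SLC18A2, a monoamine transporter, rose by 3.71 (adjusted p = 0.00614). A mast cell and basophil gene programme was tested as a candidate explanation for the rise of SIGLEC6 at 8 h. Such a list, made without SIGLEC6 and ALOX5, whose values had been seen, held 24 genes, of which 11 passed the filter on low values. Of these, 5 rose and 0 fell at 8 h with a median log2 fold change of 1.38 (unadjusted camera p = 2.26e-05, p = 0.0193 with an estimated correlation). A listed gene near 0 in untreated cells could pass that filter through treated libraries alone, which can favour a rise of this list. Unadjusted in the same way, the granulocyte and monocyte list had p = 0.00471 and the lymphocyte list p = 0.0362 with an estimated correlation, so nothing here favours mast cell genes over those. At 24 h 5 rose and 0 fell (p = 0.0141, p = 0.129 with an estimated correlation), and at 48 h 5 rose and 1 fell (p = 0.0414, p = 0.197 with an estimated correlation). The list holds GATA2, which is also among the erythroid transcription factors and was not called at 8 h (0.31). A change within K-562 cells was not separated from a change in their mixture.

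CYP1A1 is a textbook target of the aryl hydrocarbon receptor, and activation of that receptor could account for its rise from 8 h. Of 14 other listed targets, 8 passed the filter on low values. Of these, 4 rose and 0 fell at 8 h: HES1 (0.88, adjusted p = 0.00768), AHRR (0.72, adjusted p = 0.0399), TIPARP (0.47, adjusted p = 0.0417) and SLC7A5 (0.40, adjusted p = 0.0172). The list as a whole had camera p = 0.0583 at 8 h, 0.0371 at 24 h and 0.351 at 48 h, and 0.199, 0.162 and 0.51 with an estimated correlation, so it gives weak evidence. At 24 h 4 rose and 0 fell, and at 48 h, where CYP1A1 was highest, 2 rose and 1 fell, SLC7A5 (-1.19, adjusted p = 5.8e-07). SLC7A5 also belongs to the integrated stress response list, and NFE2L2 and NQO1 to the NRF2 list. TIPARP rose with time, to a mean of 7620 at 48 h from 1220 in untreated cells, while AHRR was at 223 at 48 h against 201.

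Several abundant genes were listed at low values. ACTB, beta-actin, was at 1340, 1540 and 1230 in untreated libraries and at 35200, 34800 and 40800 at 48 h. RPS27 was at 217, 218 and 246 in untreated libraries, against a median of 43200 for the ribosomal protein list, and at 1490, 1130 and 1300 at 48 h. RPS9 was listed at 358, 0 and 3.49 in untreated libraries. Genes whose principal transcripts all carry late identifiers had a median untreated value of 198 (151 genes), against 855 for the other 12473. ACTB, RPS27 and RPS9 are not among these 151 genes.

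For the comparisons of 3 libraries with 3, the 10 splits of the 6 libraries are too few for a share under 0.05. The real split gave 4347, 7343, 10207, 2798 and 8058 calls for 8, 24 and 48 h against untreated, 24 h against 8 h and 48 h against 24 h, and the highest other split gave 2, 2, 3, 2 and 3, so that 1 split, the real one, reached the real count in each. For the moderated F-test over all 12 libraries, 1 of 100 splits into 4 groups of 3 reached 11621 calls, again the real one, and the highest other gave 6762. With the real split included, 1 of 100 is the smallest share that could arise, which limits chance for that count without excluding it. The other splits mix libraries of different groups, so they give no expected size for the count.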
